A study of Mus musculus with 9 samples.

How the data were processed

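The data are a table of whole-number counts per gene for 9 RNA-seq libraries of mouse dental papilla cells, in 3 groups of 3 taken from the sample titles. The authors deposited the counts without normalization. Per the submitters' processing notes, reads were handled with fastp 0.20.0 (a read trimmer and filter), HISAT2 2.1.0 (an aligner) and featureCounts 1.6.0 (a counter), on genome build GRCm38. The annotation release, the strand setting and the way the library was selected are not given in the sources used here; the labels name the molecule as total RNA and the design text speaks of mRNA. The gene coordinates are those of the deposited count table, and 96.1% of the single-interval genes with a GENCODE M21 name have identical coordinates there. Gene types were taken from GENCODE M21.

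How the counting was done limits some measurements. The table has 53353 entries, of which 24582 have at least 1 count. For all 53245 entries with a single interval, the stated length equals the whole span from start to end, so reads in introns were counted too. Of the protein-coding genes lying wholly within genes of the opposite strand, 716 of 716 have at most 3 counts over the 9 libraries, and 297 of 297 of those wholly within genes of the same strand, against 32.1% of genes that overlap none. No level is therefore given for genes wholly inside others, such as Timp1, Igf2, Timp3 and Xist, which are listed at 0. Of the entries, 45.1% overlap another gene; where the reads of partly covered genes fall was not tested. All 37 mitochondrial entries are at 0, and 11 entries carry a date in place of a gene symbol; these were kept under that name and none was named. Of 482 genes in the fixed lists, 475 were found, 36 of these with at most 3 counts.

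Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, which left 15675 genes, and a quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest) in 1 fit of group means over all 9 libraries, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. All tests are two-sided. Changes beyond 2-fold were tested with glmTreat. The biological coefficient of variation was 4% over all libraries. Estimated by group, it was 2.5% in primary cells, 4.9% in monolayer and 4.5% in spheres, whereas the fit shared its spread over the groups. Log-CPM values used a prior count of 2. Ratios are of mean CPM; where a group had no count, a bound against 3 counts over that group is given in place of a fold. For largest changes with 1 to 10 counts in the lower group, the ratio of summed counts, scaled by the TMM library sizes, is given with a 95% exact binomial interval. TMM factors were 1.065 to 1.072 in primary cells, 0.861 to 0.882 in monolayer and 1.07 to 1.082 in spheres. The 10 most abundant genes took 17.12 to 17.83% of the counts in monolayer, against 9.87 to 9.99% in spheres and 11.49 to 11.65% in primary cells.

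Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one, adjusted over the lists of a comparison; a list needed at least 3 tested genes. The 32 lists were fixed before the data were examined, as were the grouping, the tests and the rule for named genes: 23 programs (odontoblast and mineralization, dental mesenchyme transcription factors, neural crest, pluripotency, mesenchymal stem cell markers, Wnt, Notch, BMP and TGF-beta, fibrillar matrix, basement membrane, matrix proteases, mitosis, DNA replication, p53, hypoxia, cholesterol synthesis, unfolded protein, contractile actin, YAP and SRF, inflammatory, interferon, lysosome, angiogenic and neurotrophic) and 9 sets of markers of other cell types (epithelial, endothelial, macrophage, erythroid, glial and neuronal, pericyte, skeletal muscle, adipocyte, chondrocyte). The erythroid set had too few tested genes. The estimated correlation lay below the preset one for some lists, such as p53 (-0.028), inflammatory (-0.021) and YAP and SRF (-0.04). A call lost with an estimated correlation thus need not mean that the members of the list are correlated. Another 3 lists (Hox, imprinted, and neuronal and synaptic genes) were added after values were seen. Named genes are Cd24a, then per comparison the 8 largest increases and 8 largest decreases by fitted log2 change among genes past the threshold whose groups do not overlap, with a mean of at least 10 CPM in the higher group and a symbol that is not a predicted-gene name, then up to 4 members per list with the smallest adjusted p, and any other member given with its adjusted p. Names outside this rule are stated as such.

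The tests were tried on simulated counts, with 200 genes changed, 50 per fold, and all others unchanged. Means were pooled over the 2 groups compared, dispersions came from their trend over abundance, and library sizes were the real ones. In the data 71.3 to 79.6% of the genes were called. The shares below thus hold for a setting with few changed genes and do not carry over to the data. In the comparison of spheres with monolayer, 80% of genes changed 2-fold, 78% of those changed 1.5-fold, 54% of those changed 1.25-fold and 16% of those changed 1.1-fold were recovered, with 7 unchanged genes called among 15203 tested. In that of spheres with primary cells the shares were 96%, 84%, 56% and 14%, with 4 called among 15287, and in that of monolayer with primary cells 88%, 72%, 70% and 16%, with 9 called among 15042.

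Alternatives planned in advance were DESeq2 1.42.0 size factors, upper-quartile scaling and total counts, no filter or a stricter one (1 CPM in at least 3 libraries), DESeq2 and limma-voom as tests, a fit of only the groups compared, the replicate number as a block, leaving out the 50 most abundant genes, fry in place of camera, and leaving out each library in turn. The restriction to genes whose span overlaps no other gene was added after the data were seen, as were total counts and upper-quartile scaling for the list tests. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. No library was left out of the comparisons, and 0 columns of values per sample were left unused.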

Results

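Gene expression was measured by RNA sequencing in dental papilla cells of C57BL/6 mice. The dental papilla is the mesenchyme of the tooth germ, which forms the dental pulp and the odontoblasts that make dentin. The 9 libraries fall into 3 groups of 3: primary cells, cells grown as a monolayer on plates, and cells grown as spheres. Per the labels' protocols, the monolayer medium held 2% serum and 1% growth supplement, whereas the spheres were seeded from passage 2 cells on low-attachment plates in basal medium with methylcellulose. Culture format and medium thus differ together between these groups. The source labels give 8 days of culture for monolayer and spheres, while the growth protocol gives 14 days for the monolayer and 8 days for the spheres. The design text of the series lists a group called DPC P2 where the sample labels have primary cells. The labels do not say whether the libraries of a group came from separate animals or cultures. The p-values of single genes thus measure only the spread between these libraries, which may be technical. Those of the list tests set the members against all other genes, and they do not measure a spread between animals or cultures either.

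Total counts in genes were 44620255, 47570939 and 46788004 for primary libraries 1 to 3. They were 52047254, 45440554 and 43935018 for the monolayer libraries, and 35957376, 47798401 and 50823554 for the sphere libraries. Levels are given as CPM, counts scaled to library size with TMM factors, as mean ± SD over n = 3 libraries. At this depth, a gene without a count in a group has an upper limit of 3 counts over that group, which is 0.0202 CPM in primary cells, 0.0244 CPM in monolayer and 0.0208 CPM in spheres. Such limits, and the counting intervals given for ratios, cover counting error only. The first principal component held 74.9% of the variance of log-CPM and placed the spheres, at 141.24 to 142.2, apart from primary cells, at -54.23 to -53.62, and monolayer, at -88.1 to -87.52. The second component held 19.8% and parted monolayer from primary cells. Replicate libraries had Pearson correlations of 0.998 to 0.9988 across genes, which are not independent replicates. Every replicate pair differed by more than sampling noise, with a chi-square of 2.58 to 10.32 per degree of freedom, and each library was counted as 1 replicate. This excess does not tell separate cultures from repeats of 1 culture.

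**Figure D1:**
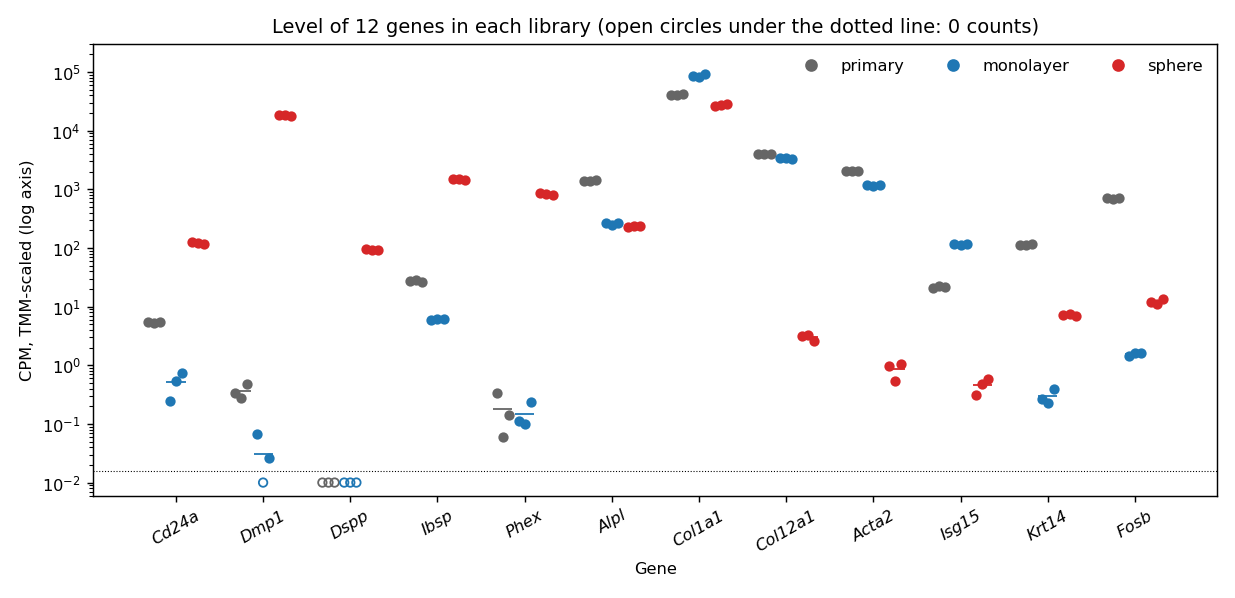
Normalised level (CPM, log axis) of 12 genes in each of the 9 libraries, with 1 point per library, coloured by group, and a line at the group mean; open circles mark libraries with 0 counts. Dmp1 stood at 18360 CPM in spheres against 0.364 CPM in primary cells and 0.031 CPM in monolayer, whereas Alpl was highest in primary cells at 1409 CPM.

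Spheres were first compared with the monolayer, a contrast of aggregates with cells on plates in which the medium, and perhaps the culture time, differed too. The series title names CD24a-positive stem cells and a complex resembling pulp and dentin. Cd24a, a lipid-anchored surface glycoprotein used as a stem cell marker (chromosome 10, 43578284 to 43584265, plus strand, GRCm38), was at 121.8 ± 2.99 CPM in spheres and 0.511 ± 0.25 CPM in monolayer, 238-fold higher (log2 change 7.93, SE 0.10, adjusted p = 2.4e-29). Dmp1, an acidic phosphoprotein of dentin and bone matrix (chromosome 5, 104202613 to 104214102), reached 18360 ± 351 CPM in spheres. Only 4 counts of Dmp1 were seen over the monolayer libraries, a ratio of 563000 with a 95% exact binomial counting interval of 220000 to 2070000. Of these counts 3 lay in monolayer library 1, without which the fitted log2 change went from 18.99 to 20.17. Dspp, which encodes the main non-collagenous proteins of dentin (chromosome 5, 104170712 to 104180127), had 94.07 ± 2.81 CPM in spheres and no count in the monolayer or in primary cells, at least 3860-fold higher than monolayer. Both genes are protein-coding, and no other gene of the annotation overlaps their spans.

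The odontoblast and mineralization list rose as a group: 15 of its 17 tested genes rose, 1 fell and 1 did not pass the test (median log2 change 5.10, adjusted p = 1.57e-07, and 0.0162 with an estimated correlation). Ibsp, the bone sialoprotein gene (chromosome 5, 104299171 to 104311469), rose 246-fold to 1483 ± 20.7 CPM, and Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050, with 21.1% of its span covered by other genes), rose 417-fold to 5444 ± 96.7 CPM. Phex, an endopeptidase that regulates phosphate and mineral (chromosome X, 157162075 to 157415312), rose from 0.149 ± 0.077 to 821.5 ± 30.2 CPM, 5500-fold (adjusted p = 1.2e-25). The osteocalcin gene Bglap rose 53.6-fold to 210 ± 9.2 CPM. Sp7, a transcription factor of osteoblasts and odontoblasts, rose 6.9-fold to 892 ± 13 CPM (adjusted p = 8.5e-30). The member that fell was Alpl, the tissue-nonspecific alkaline phosphatase (262.7 ± 11.3 against 237.3 ± 4.58 CPM, log2 change -0.15, adjusted p = 0.00021). Runx2, a transcription factor needed for osteoblast formation, did not pass, at 174 ± 6 against 178 ± 6.3 CPM (adjusted p = 0.39).

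**Figure D2:**
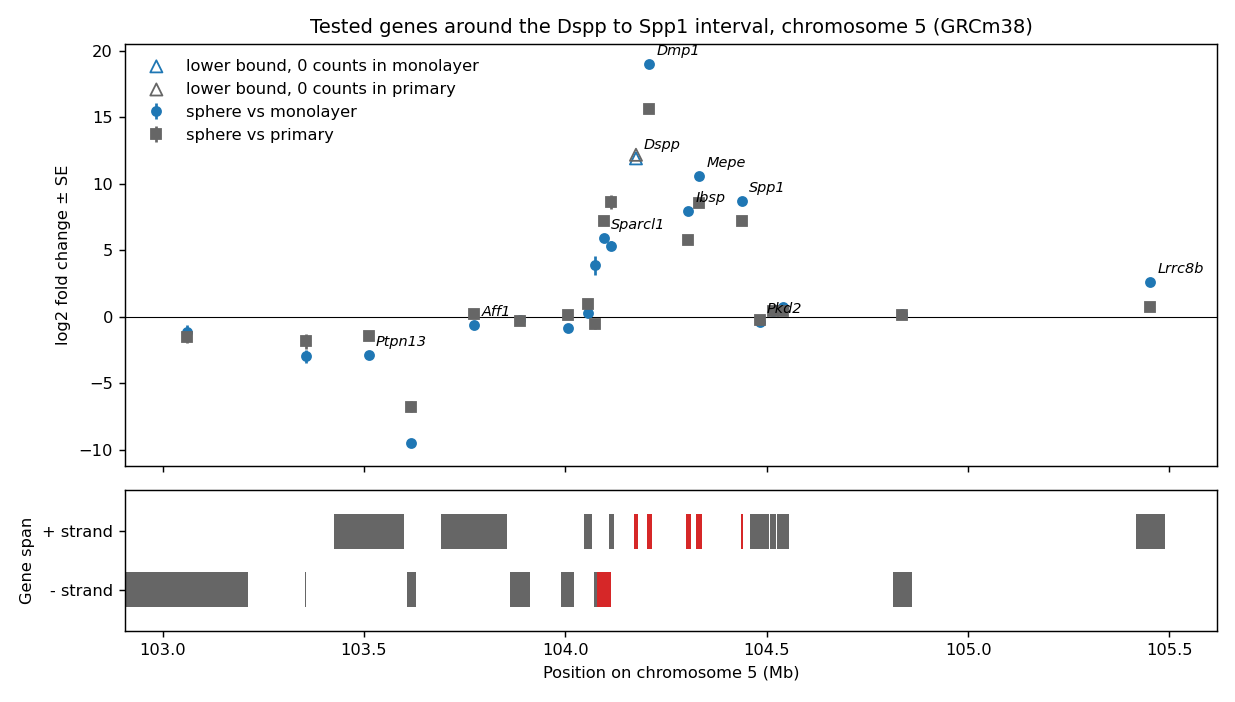
Log2 fold change of spheres against monolayer (circles) and against primary cells (squares), with its SE, for tested genes around Dspp and Spp1 by position on chromosome 5 (Mb, GRCm38), above the spans of the genes by strand; triangles mark lower bounds for a gene without a count in the other group, and red spans mark Sparcl1, Dspp, Dmp1, Ibsp, Mepe and Spp1. Against monolayer, these rose by 5.89 (Sparcl1) to 18.99 (Dmp1, or 20.17 without monolayer library 1) log2 units, while Pkd2, just beyond Spp1, was at 179.3 CPM in spheres and 232.4 CPM in monolayer (Sparcl1, Mepe and Pkd2 were chosen after their values were seen).

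Genes of the extracellular matrix and of the contractile apparatus were lower in spheres. In the fibrillar collagen and matrix list 17 of 19 genes fell and 2 rose (median log2 change -3.02, adjusted p = 4.89e-09, and 0.0158 with an estimated correlation). Postn, which encodes the matrix protein periostin, went from 4253 ± 189 to 18.3 ± 0.6 CPM, 232-fold lower. Col3a1, the type III collagen chain, was 36.9-fold lower at 290 ± 5.8 CPM, and Fn1, fibronectin, was 12.5-fold lower at 398 ± 2.1 CPM. The contractile actin list fell in all of its 14 genes (median -3.99, adjusted p = 4.25e-08, and 0.0288 with an estimated correlation). Acta2, smooth muscle actin, went from 1160 ± 23 to 0.863 ± 0.28 CPM, 1340-fold lower, and the calponin gene Cnn2 was 18.8-fold lower at 49.9 ± 0.62 CPM. Basement membrane genes fell in 11 of 12 cases and rose in 1, with an adjusted p of 2.01e-05, but adjusted p = 0.106 with an estimated correlation. Among them, the laminin chain gene Lama2 was 65.8-fold lower and the nidogen gene Nid2 147-fold lower. In the list of matrix proteases and inhibitors 10 of 12 genes fell and none rose (adjusted p = 2.38e-05, and 0.0719 with an estimated correlation). The collagenase gene Mmp13 was 49.7-fold lower in spheres, at 14.5 ± 0.94 CPM.

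All 16 tested interferon response genes fell in spheres (median log2 change -7.12, adjusted p = 8.34e-09, and 0.00908 with an estimated correlation). Isg15, a ubiquitin-like modifier induced by interferon, went from 116 ± 3.4 to 0.461 ± 0.14 CPM, and Ifit1 from 169 ± 11 to 0.581 ± 0.2 CPM. All 17 cholesterol synthesis genes fell as well (median -3.08, adjusted p = 8.85e-10, and 0.00908 with an estimated correlation). Among them, Dhcr7, the last enzyme of the pathway, was 8.6-fold lower. The 18 mitosis genes fell by less (median -0.81, adjusted p = 0.000237, and 0.0288 with an estimated correlation), for example the cyclin-dependent kinase gene Cdk1, from 15.1 ± 1.2 to 4.41 ± 0.22 CPM. Hypoxia and glycolysis genes rose in 16 of 19 cases, with 1 lower and 2 not passing (median 1.02, adjusted p = 2.38e-05, and 0.047 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase induced by hypoxia, rose 3.01-fold and the lactate dehydrogenase gene Ldha 2.54-fold. Unfolded protein and amino acid stress genes rose in 11 of 15 cases and fell in 4 (adjusted p = 0.00527, and 0.0856 with an estimated correlation), with the stress-induced transcription factor gene Atf3 40.3-fold and Trib3 6.04-fold higher. The 4 that fell were Manf (log2 change -0.33, adjusted p = 8.89e-09), Sdf2l1 (-0.29, 0.000149), Creld2 (-0.25, 0.000221) and Hspa5 (-0.08, 0.0159, but 0.0543 without sphere library 2 and 0.0748 without sphere library 3); scaled to total counts, 12 genes of this list rose and 0 fell. Of the p53 target and cell cycle inhibitor genes, 9 of 14 fell and 3 rose (adjusted p = 0.0398, and 0.106 with an estimated correlation). Cdkn1c, which encodes the inhibitor p57, was 23-fold lower, with 32.9% of its span covered by other genes, whereas Cdkn1a, the p21 gene, rose 1.68-fold to 1200 ± 16 CPM (adjusted p = 2.2e-18).

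No shift as a group passed the test for the other program lists, although single members changed, as did 78.4% of all genes tested. Mesenchymal stem cell surface markers rose in 8 and fell in 7 of 16 cases (adjusted p = 0.85): the intermediate filament gene Nes rose 375-fold to 649 ± 5.5 CPM and Nt5e, the CD73 gene, 17.7-fold, whereas Pdgfrb was 35.9-fold lower. The median log2 change of that list was 0.12, its mean -0.08 and its test pointed up. Dental mesenchyme transcription factors rose in 6 and fell in 9 of 16 cases (adjusted p = 0.376), with Dlx3 8.93-fold higher and Pax9 6.67-fold lower. Wnt target and feedback genes rose in 10 and fell in 6 of 17 cases (adjusted p = 0.312), among them Lgr6, an R-spondin receptor, 124-fold higher at 645 ± 12 CPM and the secreted Wnt inhibitor Sfrp1 89.4-fold lower. Notch pathway genes gave 5 higher and 4 lower of 12 (adjusted p = 0.353), with the target Hes1 9.52-fold higher. BMP and TGF-beta response genes gave 10 higher and 6 lower of 16 (adjusted p = 0.317), with the pseudoreceptor gene Bambi 42.5-fold higher and the BMP antagonist Grem1 77.6-fold lower. Counts of higher and lower genes were 4 and 5 of 9 for neural crest genes (adjusted p = 0.5), 2 and 5 of 7 for pluripotency and reprogramming genes (adjusted p = 0.376) and 6 and 9 of 17 for DNA replication genes (adjusted p = 0.5). They were 5 and 9 of 15 for YAP and SRF targets (adjusted p = 0.139), 12 and 5 of 19 for lysosome genes (adjusted p = 0.139), and 3 and 10 of 14 for angiogenic and neurotrophic factors (adjusted p = 0.128). Inflammatory cytokine and chemokine genes rose in 4 and fell in 6 of 12 cases (adjusted p = 0.311), with a median of -0.26, a mean of 0.07 and a test pointing down.

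Markers of other cell types differed too. Epithelial markers rose in 12 and fell in 2 of 16 cases (median log2 change 3.99, adjusted p = 0.00187, and 0.0458 with an estimated correlation), and their summed level was 692 ± 5.9 CPM in spheres against 34.6 ± 1.5 CPM in monolayer. Of this sum, Ambn, the enamel and root matrix protein ameloblastin, gave 524 ± 6.2 CPM; the adhesion gene Epcam had 42.9 ± 1.8 CPM. Macrophage and leukocyte markers rose in 11 and fell in 2 of 13 cases, at a summed 58.2 ± 1.1 against 16 ± 1.2 CPM (adjusted p = 0.0152, and 0.106 with an estimated correlation). The remaining marker lists did not pass: endothelial (2 higher and 4 lower of 8, adjusted p = 0.312, median -2.36, or -1.36 with the gene at 0 set to its bound) and glial and neuronal (2 and 3 of 5, adjusted p = 0.376). Nor did pericyte (4 and 2 of 6, adjusted p = 0.265), skeletal muscle (0 and 2 of 3, adjusted p = 0.507), adipocyte (3 and 1 of 4, adjusted p = 0.376) or chondrocyte markers (1 and 5 of 7, adjusted p = 0.169). Erythroid markers had too few tested genes for a test and summed to 0.929 ± 0.14 CPM in spheres and 0.00832 ± 0.014 CPM in monolayer.

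Of 15675 genes tested with edgeR, 6382 were higher and 5905 lower in spheres than in monolayer at an adjusted p of 0.05, and 1975 and 2407 when the change was tested against 2-fold. The groups did not overlap for 78.3% of the genes, against 10% by chance. By fitted log2 change, the largest increases beside Dmp1, Dspp and Phex were those of the glutamate decarboxylase gene Gad2 (45.54 CPM, at least 1870-fold) and the immune receptor gene Cd300lb (26.65 CPM, at least 1090-fold). Next came the long non-coding RNA BC055402 (17.77 CPM, at least 729-fold), the contactin gene Cntn3 (15.94 CPM, at least 654-fold) and Lingo3 (350 CPM, a ratio of 6210 with a counting interval of 3020 to 15500). By the same measure, the largest decreases included those of Prelp (176.8 CPM in monolayer, ratio 8520, interval 2920 to 41300, with 40.7% of its span covered by other genes), Megf6 (1112 CPM, 7180-fold lower) and the junctophilin gene Jph2 (900 CPM, 5840-fold lower). They also included the muscle ankyrin repeat gene Ankrd1 (11.91 CPM, at least 574-fold lower), the oligoadenylate synthetase gene Oas2 (27.99 CPM, ratio 4050, interval 727 to 160000), the flavin monooxygenase gene Fmo2 (329.6 CPM, 2230-fold lower) and Marc1 (19.48 CPM, ratio 2820, interval 505 to 111000). In spheres, the counts of Prelp (3), Oas2 (1) and Marc1 (1) lay in library 3, library 1 and library 2 in that order, without which each gene was at 0 in spheres. Of the 13 list calls in this comparison, 8 held with an estimated correlation. For every list, the counts of higher and lower members adjusted over the list alone equalled those adjusted over all genes.

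Scaling to total counts, chosen for the lists after seeing the data, which shifted all genes by 0.30 on the log2 scale, raised the share of higher genes among those called from 51.9% to 67.4%. It ended the calls of the p53 list (adjusted p = 0.0707) and the macrophage list (adjusted p = 0.0869), and gave calls to the lysosome (17 higher and 0 lower, adjusted p = 0.00475), YAP and SRF (0.0456), angiogenic (0.0213) and chondrocyte (0.0456) lists. It turned the inflammatory median from -0.26 to 0.05 and the stem cell marker test downward (adjusted p = 0.628), and all 17 odontoblast genes, including Alpl (0.16) and Runx2 (0.27), rose under it. Restricted to genes whose span overlaps no other gene, also chosen after seeing the data, the basement membrane (adjusted p = 0.164), p53 (adjusted p = 0.0613) and unfolded protein (adjusted p = 0.144) calls were lost, and the BMP and TGF-beta (median 0.72, adjusted p = 0.0319) and chondrocyte (-3.59, 0.0152) lists passed. The p53 call was also lost without sphere replicate 1 (adjusted p = 0.0578).

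**Figure D3:**
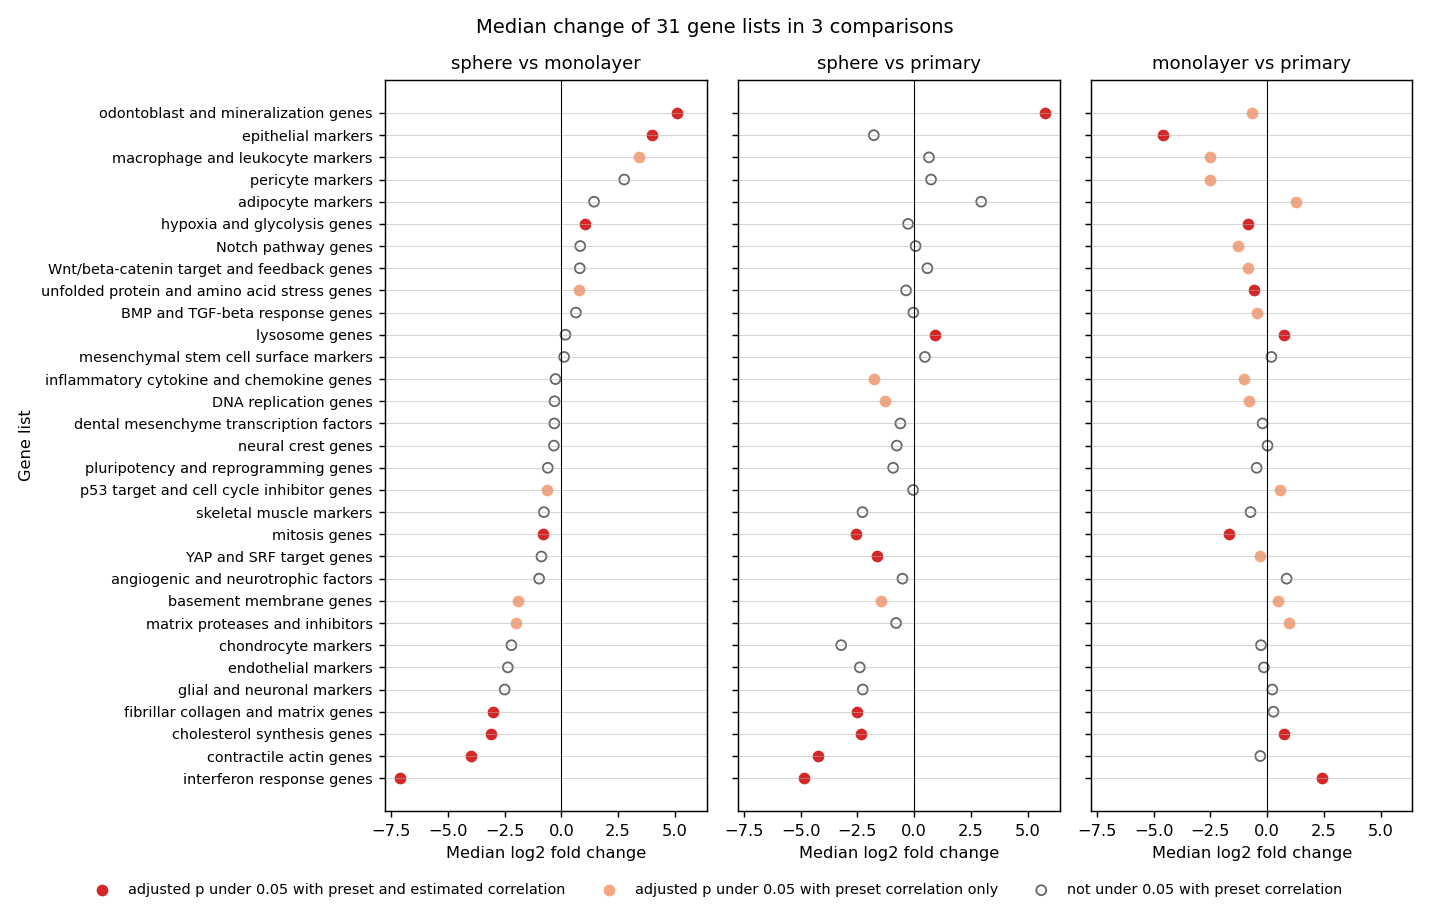
Median log2 fold change of the 31 tested gene lists (vertical axis) in the 3 comparisons (one panel each); red points passed the list test with the preset and the estimated correlation, orange points with the preset one only, and open points did not pass with the preset one. The odontoblast list lay at 5.10 and 5.76 in the comparisons of spheres with monolayer and with primary cells, and at -0.68 in that of monolayer with primary cells.

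Spheres were next compared with the primary cells. Cd24a was at 5.44 ± 0.092 CPM in primary cells and rose 22.4-fold in spheres (log2 change 4.48, SE 0.067, adjusted p = 1.2e-27). The odontoblast and mineralization list rose in 15 of 17 cases and fell in 2 (median log2 change 5.76, adjusted p = 8.82e-07, and 0.0131 with an estimated correlation). Dmp1 rose 50400-fold from 0.364 ± 0.107 CPM, Dspp at least 4660-fold, Spp1 148-fold from 36.7 ± 0.726 CPM, Ibsp 54.4-fold from 27.3 ± 1.3 CPM and Bglap 85.1-fold from 2.47 ± 0.21 CPM. The 2 genes that fell were Alpl, 5.94-fold lower from 1409 ± 16.4 CPM (adjusted p = 5.4e-29), and Runx2, 1.19-fold lower from 208 ± 2.5 CPM (adjusted p = 2.7e-07).

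Proliferation genes were lower in spheres than in primary cells. All 18 mitosis genes fell (median log2 change -2.57, adjusted p = 3.51e-08, and 0.00765 with an estimated correlation). The proliferation marker Mki67 went from 55.3 ± 1.4 to 8.46 ± 0.54 CPM and the topoisomerase gene Top2a from 64.7 ± 3.6 to 11.4 ± 0.68 CPM. DNA replication genes fell in 14 of 17 cases and rose in 2 (adjusted p = 0.00127, and 0.0508 with an estimated correlation), with the ribonucleotide reductase genes Rrm1 and Rrm2 10.9-fold and 5.2-fold lower. Fibrillar collagen and matrix genes fell in 18 of 19 cases and rose in 1 (median -2.54, adjusted p = 8.24e-10, and 0.00765 with an estimated correlation), with Postn 170-fold, Col3a1 30.4-fold and Fn1 14-fold lower. Contractile actin genes fell in all 14 cases (median -4.25, adjusted p = 2.74e-08, and 0.0198 with an estimated correlation), and YAP and SRF targets in 13 of 15 with 1 higher (adjusted p = 8.94e-07, and 0.00765 with an estimated correlation). Among the latter, Cyr61, a matricellular protein, was 33.8-fold lower and Amotl2 64-fold lower. Interferon response genes fell in all 16 cases (median -4.86, adjusted p = 5.65e-07, and 0.00765 with an estimated correlation), and cholesterol synthesis genes in 16 of 17 with 1 higher (adjusted p = 2.74e-08, and 0.00765 with an estimated correlation).

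Lysosome genes rose in all 19 cases (median log2 change 0.91, adjusted p = 1.72e-08, and 0.00765 with an estimated correlation), including the cathepsin gene Ctsk, from 184 ± 2.5 to 1140 ± 13 CPM, and Gpnmb, from 617 ± 8.4 to 2676 ± 20.6 CPM. Basement membrane genes fell in 11 of 12 cases and rose in 1 (adjusted p = 1.95e-05, and 0.132 with an estimated correlation). Inflammatory genes fell in 10 of 12 and rose in 1 (adjusted p = 0.00488, and 0.0508 with an estimated correlation), with the macrophage growth factor gene Csf1 67.5-fold lower at 16 ± 0.093 CPM. The other program lists did not pass. Mesenchymal stem cell markers rose in 8 and fell in 8 of 16 cases (adjusted p = 0.907, median 0.47, mean -0.69, test pointing up); Pdgfrb was 29-fold lower and Nes 25.4-fold higher. Counts of higher and lower genes were 6 and 9 of 16 for dental mesenchyme transcription factors (adjusted p = 0.415), 3 and 5 of 9 for neural crest genes (adjusted p = 0.372), 1 and 6 of 7 for pluripotency genes (adjusted p = 0.1). They were 7 and 8 of 16 for BMP and TGF-beta response genes (adjusted p = 0.907), 4 and 8 of 12 for matrix proteases (adjusted p = 0.228), 7 and 6 of 14 for the p53 list (adjusted p = 0.897). They were 8 and 10 of 19 for hypoxia genes (adjusted p = 0.907), 3 and 11 of 15 for the unfolded protein list (adjusted p = 0.116) and 3 and 10 of 14 for angiogenic and neurotrophic factors (adjusted p = 0.247). In the last of these, Igf1 was 80.6-fold lower and Pdgfa 10.7-fold higher. Wnt target genes gave 9 higher and 7 lower of 17 (adjusted p = 0.852, median 0.58, mean -0.08, test pointing up) and Notch genes 6 and 6 of 12 (adjusted p = 0.907, median 0.06, mean -0.10, test pointing down).

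Epithelial markers went both ways: 4 rose and 12 fell of 16 (adjusted p = 0.228), with Ambn 14-fold and Epcam 14.9-fold higher in spheres (Epcam adjusted p = 6.9e-24) and the basal keratin genes Krt14 and Krt5 15.6-fold and 24-fold lower. Their summed level was 296 ± 3 CPM in primary cells. Of the macrophage and leukocyte markers 9 rose and 3 fell of 13 (adjusted p = 0.325), with the lysozyme gene Lyz2 2.2-fold higher at 27.4 ± 0.61 CPM. Summed levels in spheres against primary cells were 2.91 ± 0.26 and 23.1 ± 0.59 CPM for endothelial markers (1 higher and 5 lower of 8, adjusted p = 0.211), 18.7 ± 1.1 and 19.8 ± 0.95 CPM for glial and neuronal markers (1 and 3 of 5, adjusted p = 0.348), and 576 ± 23 and 245 ± 0.91 CPM for pericyte markers (3 and 2 of 6, adjusted p = 0.593). They were 1.24 ± 0.21 and 4.88 ± 0.3 CPM for skeletal muscle markers (0 and 3 of 3, adjusted p = 0.3), 173 ± 8.3 and 41.3 ± 1.5 CPM for adipocyte markers (3 and 1 of 4, adjusted p = 0.228), and 144 ± 6.3 and 1470 ± 24 CPM for chondrocyte markers (1 and 6 of 7, adjusted p = 0.13). The chondrocyte sum fell mainly with Col11a1, a fibrillar collagen chain, 96-fold lower at 14.8 ± 0.17 CPM.

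With edgeR, 6102 genes were higher and 6370 lower in spheres than in primary cells, and 1766 and 2582 when tested against 2-fold. The groups did not overlap for 81.2% of the genes, against 10% by chance. Beside Dmp1, Dspp and Phex (4610-fold; log2 change 12.17, or 12.97 without primary library 1), the largest increases by fitted log2 change were those of Gad2 (at least 2250-fold) and the glutamate receptor gene Grik2 (96.4 CPM, ratio 4760, interval 1630 to 23100). Next came Adamtsl2 (137.2 CPM, ratio 2270, interval 1200 to 4980), Trim54 (12.85 CPM, ratio 1910, interval 342 to 75300) and the activin receptor gene Acvr1c (70.74 CPM, ratio 1310, interval 664 to 3030). The largest decreases by that measure were those of Megf6 (1447 CPM in primary cells, 9340-fold lower), Ankrd1 (18.97 CPM, at least 914-fold lower), the chemokine receptor gene Ackr1 (16.46 CPM, at least 793-fold lower, with 26.4% of its span covered by other genes). Next came Acta2 (2068 CPM, 2400-fold lower), Chodl (45.81 CPM, ratio 2210, interval 755 to 10700), the endothelin gene Edn3 (15.72 CPM, ratio 2280, interval 408 to 90000), Jph2 (226.8 CPM, 1470-fold lower) and the collagen gene Col12a1 (4017 to 3.002 CPM, 1340-fold lower). The single count of Trim54 in primary cells lay in library 1 and that of Edn3 in spheres in library 3, without which each was at 0 there, and the log2 change of Chodl went from -10.93 to -11.88 without sphere library 1. Of the 11 list calls 8 held with an estimated correlation, and counts adjusted over the list alone were equal for every list. The basement membrane call was also lost with genes whose span overlaps no other gene (adjusted p = 0.126), and the unfolded protein (median -0.45, adjusted p = 0.00776) and chondrocyte (-3.51, 0.0144) lists passed. Without a low-count filter, the pluripotency (adjusted p = 0.0403), unfolded protein (0.0341) and chondrocyte (0.0311) lists passed, and upper-quartile scaling turned the Notch median from 0.06 to -0.02.

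Monolayer was last compared with the primary cells. No culture time or medium is given here for the primary cells, so the differences cannot be assigned to flat culture alone. Cd24a fell 10.7-fold (log2 change -3.45, SE 0.16, adjusted p = 1.9e-16). Interferon response genes rose in all 16 cases (median log2 change 2.40, adjusted p = 1.23e-07, and 0.00938 with an estimated correlation). Ifit1 rose 11.2-fold from 15.2 ± 0.46 to 169 ± 11 CPM and Oasl2 7-fold from 29.6 ± 0.23 to 207 ± 4.2 CPM. All 17 cholesterol synthesis genes rose (median 0.73, adjusted p = 1.65e-07, and 0.00938 with an estimated correlation), with the regulator Insig1 1.99-fold higher at 505 ± 2.8 CPM. Lysosome genes rose in 17 and fell in 2 of 19 cases (median 0.76, adjusted p = 1.65e-07, and 0.0107 with an estimated correlation), Ctsk by 6.63-fold. Mitosis genes fell in all 18 cases (median -1.69, adjusted p = 2.29e-08, and 0.00938 with an estimated correlation), with Mki67 3.76-fold lower at 14.7 ± 0.74 CPM. Hypoxia and glycolysis genes fell in 17 and rose in 1 of 19 cases (median -0.84, adjusted p = 2.58e-07, and 0.0234 with an estimated correlation). The growth factor gene Vegfa was 3.13-fold lower and the glucose transporter gene Slc2a1 3.72-fold lower. Unfolded protein and amino acid stress genes fell in 14 and rose in 1 of 15 cases (median -0.59, adjusted p = 2.58e-07, and 0.0118 with an estimated correlation), with Trib3, a pseudokinase induced by amino acid stress, 13.3-fold lower and Atf3 36.8-fold lower.

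Epithelial markers fell in 15 and rose in 1 of 16 cases from primary cells to monolayer (median log2 change -4.60, adjusted p = 2.67e-06, and 0.0108 with an estimated correlation). Krt14 went from 113 ± 2.4 to 0.296 ± 0.09 CPM and Krt5 from 57.6 ± 2.1 to 0.175 ± 0.06 CPM. Macrophage and leukocyte markers fell in 10 and rose in 1 of 13 cases (adjusted p = 0.00567, and 0.0717 with an estimated correlation). Pericyte markers fell in 5 and rose in 1 of 6 (adjusted p = 0.0274, and 0.146 with an estimated correlation), and adipocyte markers rose in 3 of 4 (adjusted p = 0.0274, and 0.1 with an estimated correlation). Endothelial markers gave 3 higher and 3 lower of 8 (adjusted p = 0.95), glial and neuronal markers 2 and 2 of 5 (adjusted p = 0.618), skeletal muscle markers 0 and 2 of 3 (adjusted p = 0.33) and chondrocyte markers 1 and 4 of 7 (adjusted p = 0.763). The erythroid sum was 0.00654 ± 0.011 CPM in primary cells.

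Another 10 list calls of this comparison were lost with an estimated correlation. For the p53, inflammatory and YAP and SRF lists among them, that estimate lay below the preset one. Odontoblast and mineralization genes fell in 11 and rose in 2 of 17 cases (adjusted p = 0.00567, and 0.0729 with an estimated correlation), with Alpl 5.36-fold lower. Matrix proteases and inhibitors rose in 11 and fell in 1 of 12 cases (adjusted p = 1.66e-05, and 0.0673 with an estimated correlation), with Mmp13 5.99-fold higher. Wnt target and feedback genes fell in 13 and rose in 1 of 17 cases (adjusted p = 0.00206, and 0.132 with an estimated correlation), with the Wnt inhibitor Wif1 8.12-fold lower. Notch pathway genes fell in 8 and rose in 1 of 12 (adjusted p = 0.00761, and 0.1 with an estimated correlation), with Hes1 7.52-fold lower. BMP and TGF-beta response genes fell in 11 and rose in 4 of 16 cases (adjusted p = 0.0299, and 0.237 with an estimated correlation). DNA replication genes fell in 13 and rose in 2 of 17 (adjusted p = 0.00444, and 0.0717 with an estimated correlation). The p53 target and cell cycle inhibitor genes rose in 10 and fell in 4 of 14 (adjusted p = 0.0136, and 0.0717 with an estimated correlation). Among them, the inhibitor gene Cdkn2a was 5.64-fold higher. YAP and SRF targets fell in 10 and rose in 5 of 15 cases (adjusted p = 0.0274, and 0.0959 with an estimated correlation). The immediate early genes Fosb and Fos were 452-fold and 26.7-fold lower. Inflammatory genes fell in 8 of 12 cases and rose in none (adjusted p = 0.00444, and 0.0605 with an estimated correlation). The basement membrane genes rose in 8 and fell in 3 of 12 (adjusted p = 0.0161, and 0.278 with an estimated correlation), with the type IV collagen gene Col4a1 4.97-fold higher and Lama1 33.2-fold lower.

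Fibrillar collagen and matrix genes rose in 10 and fell in 8 of 19 cases from primary cells to monolayer (adjusted p = 0.152). Col1a2 rose 3.02-fold to 46420 ± 880 CPM, and both type I collagen genes together took 11.61 ± 0.336% of the counts in monolayer, 6.08 ± 0.06% in primary cells and 3.76 ± 0.108% in spheres. Contractile actin genes rose in 2 and fell in 9 of 14 cases (adjusted p = 0.0784, and 0.0341 without sphere replicate 2). Counts of higher and lower genes were 7 and 9 of 16 for dental mesenchyme transcription factors (adjusted p = 0.788), 1 and 4 of 7 for pluripotency genes (adjusted p = 0.115) and 9 and 5 of 14 for angiogenic and neurotrophic factors (adjusted p = 0.121). Neural crest genes gave 2 higher and 4 lower of 9 (adjusted p = 0.817, median 0.02, mean -0.38, test pointing down) and mesenchymal stem cell markers 9 and 7 of 16 (adjusted p = 0.95, median 0.19, mean -0.62, test pointing up).

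With edgeR, 5389 genes were higher and 5787 lower in monolayer than in primary cells, and 968 and 1226 when tested against 2-fold. Which direction held more genes depended on the scaling. Median-ratio size factors gave 5751 higher and 5420 lower, and upper-quartile scaling 4743 and 6515. The groups did not overlap for 74.4% of the genes, against 10% by chance. By fitted log2 change, the largest increases included those of Fmo2 (0.772 to 329.6 CPM, 427-fold) and the interferon-inducible genes Ifi207 (127-fold) and Ifi205 (39.1-fold). Others were Clca3a1 (95.6-fold), the stromelysin gene Mmp10 (78.3-fold), the vesicular glutamate transporter gene Slc17a8 (66.1-fold) and Galnt15 (49.2-fold). The largest decreases, beside Fosb, Krt14 (381-fold) and Krt5 (329-fold), were those of Odam (ratio 1250, interval 223 to 49200), Krt6b (ratio 612, interval 239 to 2250), Krt16 (ratio 444, interval 151 to 2150), Krt17 (293-fold) and Krt6a (100-fold). In monolayer, the 1 count of Odam lay in library 2 and the 3 counts of Krt16 in library 1, without which each was at 0 there. Of the 20 list calls 7 held with an estimated correlation, and counts adjusted over the list alone were equal for every list.

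Scaling to total counts shifted the comparison of monolayer with primary cells by -0.30 on the log2 scale, so that 25.6% in place of 48.2% of the called genes were higher (3042 higher and 8856 lower). It turned the medians of the fibrillar matrix list (0.28 to -0.02), the stem cell marker list (0.19 to -0.10), the neural crest list (0.02 to -0.28) and the glial and neuronal list (0.23 to -0.07). It also ended the calls of the odontoblast (adjusted p = 0.0685), Notch (0.0612), BMP (0.0696), macrophage (0.0581) and pericyte (0.112) lists and gave a call to the angiogenic list (0.015). With genes whose span overlaps no other gene, the Notch (adjusted p = 0.104), BMP (0.0564), YAP (0.0981) and pericyte (0.156) calls were lost, and the basement membrane list turned to a downward test (adjusted p = 0.87). The fibrillar matrix (median 0.64, adjusted p = 0.0369), contractile actin (-0.63, 0.0118) and pluripotency (-0.86, 0.0126) lists passed there, and the contractile actin list also without a low-count filter (adjusted p = 0.0328).

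Across the 3 groups, 14213 of 15675 genes differed. In spheres, 4644 genes were higher than in both other groups, 1282 of them by a test against 2-fold in both, and 4484 were lower, 1734 of them against 2-fold. Both comparisons share the sphere libraries. In 20 simulations of unchanged groups the count was 0. Even single comparisons there called at most 2 genes, so this does not measure the effect of sharing. Independent lists of the observed sizes would share 2484 higher and 2400 lower genes. Part of the excess may come from the shared sphere libraries. Cd24a, Dmp1, Dspp, Ibsp, Spp1, Bglap, Phex, Nes, Lgr6 and Bambi were among the genes higher in spheres than in both other groups, and Postn, Col3a1, Fn1, Acta2, Isg15, Mki67, Megf6, Jph2 and Ankrd1 among those lower.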

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

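The restriction to genes overlapping no other gene, and the list tests under total counts and upper-quartile scaling, were chosen after seeing the data. Of the recomputed counts of changed genes, 166 stayed within 1.5 times the main count and 19 did not. Tested against 2-fold, the counts were 1975 higher and 2407 lower (spheres against monolayer), 1766 and 2582 (spheres against primary cells), 968 and 1226 (monolayer against primary cells), and 1282 and 1734 (spheres against both), since small changes no longer count. With non-overlapping genes, 8062 genes were tested and the same counts were 3293 and 2968, 3095 and 3267, 2728 and 2983, and 2379 and 2256, with 7230 differing among the 3 groups, since fewer genes were tested. Under total counts, monolayer against primary cells gave 3042 higher and 8856 lower, as this scaling shifts all genes by -0.30. With each library left out in turn, the counts ranged over 6219 to 6434 and 5749 to 5936, 5953 to 6247 and 6199 to 6513, 5131 to 5501 and 5469 to 5918, 4520 to 4694 and 4357 to 4481, and 14155 to 14326 among the 3 groups. Of the list results, 1448 kept direction and call, 61 gained a call (44 of these with fry), 37 lost one and 26 turned in the direction of the test, 21 of these without passing in either setting. Of the other 5, 4 came with fry, which asks whether a list moves without comparing it with other genes: adipocyte markers in spheres against monolayer (median 1.44, adjusted p = 1.83e-06), hypoxia genes in spheres against primary cells (-0.27, 0.000684), and stem cell markers (0.19, 6.05e-05) and chondrocyte markers (-0.27, 0.00722) in monolayer against primary cells. The last was the basement membrane list in monolayer against primary cells with non-overlapping genes (0.08, adjusted p = 0.87); the cause was not tested. Of the 44 list calls, total counts ended 7, all of which an estimated correlation also ended, and added 5, while median-ratio and upper-quartile scaling ended 0 and added 0. Of the values of named genes, 8412 kept direction and call, 21 lost the call (Snap25, Mylpf, Tnnt3, Des, Tek, Snai2, Manf and Hspa5), 3 gained one (Junb) and 13 turned. Of these, 5 came with total counts in spheres against monolayer: Alpl (0.16, adjusted p = 2.16e-05), Runx2 (0.27, 8.3e-08), Sdf2l1 (0.02, 0.783), Creld2 (0.06, 0.356) and Hspa5 (0.23, 3.55e-08), as this scaling shifts all genes up by 0.30. The other 8, without a call in either setting, were Mylpf in spheres against monolayer (-0.06; total counts 0.24; a library left out, -0.47 to 0.24) and Fabp4 in monolayer against primary cells (-0.03; median-ratio scaling and DESeq2 0.01; a library left out, -0.17 to 0.08), both near 0. Depth limits genes near 3 counts per group. In the simulations 14 to 16% of 1.1-fold changes were recovered, which holds for few changed genes and does not carry over to the data.

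The 21 list results that turned without a call, by median, were as follows. In monolayer against primary cells, stem cell markers turned with median-ratio scaling (0.23), total counts (-0.10), non-overlapping genes (0.28) and a library left out (0.17 to 0.20), endothelial markers with upper-quartile scaling (-0.22), total counts (-0.44), non-overlapping genes (0.32) and a library left out (-0.39 to 0.13), chondrocyte markers with total counts (-0.56) and non-overlapping genes (0.08), glial and neuronal markers without the filter (-1.14) and neural crest genes with non-overlapping genes (0.13). In spheres against primary cells, Notch (0.37), BMP and TGF-beta (0.15), p53 (0.22) and hypoxia (0.15) genes turned with non-overlapping genes and stem cell markers with a library left out (0.44 to 0.47), and in spheres against monolayer stem cell markers did with total counts (0.42).

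With the replicate block, the counts were 6368 higher and 5897 lower, 6088 and 6351, 5354 and 5757, 4637 and 4472, and 14142 among the 3 groups. Same-numbered libraries correlated at -0.039 to 0.163, with 2 of 9 pairs above 0.1, and differently numbered ones at -0.182 to 0.185. No pairing by number was thus seen, but a weak one is not excluded.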

Other observations

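The tests of overlapping genes, of the epithelial markers (Epcam and Ambn included) and of chromosome copy number were chosen after their results were seen, and the genes named in this and the next paragraph, and H19, Meg3, Mest, Plagl1 and Dlk1, were chosen after their values were seen. Klk4, which encodes a protease of the enamel matrix, had 102.8 ± 5.34 CPM in spheres, 0.124 ± 0.11 CPM in primary cells and in monolayer 0.0148 ± 0.026 CPM (adjusted p = 4.59e-27 against monolayer and 3.38e-27 against primary cells); its 2 monolayer counts were both in library 1, and the log2 change against primary cells was 9.70, or 10.68 without primary library 1. Mepe, a matrix phosphoglycoprotein gene of bone and dentin, had 29.57 ± 1.22 CPM in spheres, a ratio of 1830 to the 2 counts of the monolayer (interval 505 to 15100), both of them in library 2, and was 394-fold higher than in primary cells. Sost, which encodes the Wnt antagonist sclerostin of osteocytes, had 2.18 ± 0.37 CPM in spheres and was listed at 0 in both other groups (adjusted p = 1.97e-11 and 7.67e-12). Fgf23, a phosphate-regulating hormone gene, had 3.52 ± 0.39 CPM in spheres and 0.0812 ± 0.092 CPM in primary cells (log2 change 5.39, adjusted p = 4.02e-12, but 4.80 without primary library 2 and 6.72 without primary library 3). The transcription factor gene Irx5 was 24.6-fold higher in spheres than in monolayer, at 344.8 ± 19.7 CPM (adjusted p = 1.09e-29), and Ltbp3, which encodes a binding protein of latent TGF-beta, 7.33-fold higher at 3086 ± 138 CPM (adjusted p = 3.64e-25).

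Of the immediate early genes, Jun was at 367.4 ± 4.87 CPM in primary cells and 49.31 ± 3.44 CPM in spheres (adjusted p = 7.48e-28), whereas Junb was at 217.9 ± 4.8 and 204.8 ± 17 CPM (adjusted p = 0.127, but 0.00724 with upper-quartile scaling, 0.0204 without the low-count filter and 0.0211 without sphere library 3). Lars2, the mitochondrial leucyl-tRNA synthetase gene, had 256 CPM in monolayer library 3 against 115 and 117 CPM in the other monolayer libraries, and 514 to 535 CPM in spheres.

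The first pattern is that epithelial markers were higher in primary cells than in monolayer. A shift from scaling is argued against by their median log2 change of -4.60, against a shift of -0.30 for total counts. Of the 16 tested markers 13 fell by more than 2-fold, led by Krt14 at 112.7 CPM in primary cells, but this count restates the pattern, so epithelial cells among the primary cells and a change of these genes within the cells cannot be told apart. For Epcam and Ambn, which were higher in spheres than in primary cells, more epithelial cells of the primary kind are argued against, since 12 of the other 14 markers fell (median -2.39). For Epcam and Ambn, a change within the mesenchymal cells, or epithelial cells of another kind, stays open and was not tested.

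The second pattern is that the sphere libraries stood far apart from both other groups. Cells of a Hox-expressing tissue are argued against by a summed level of 39 Hox genes of 0.0947 CPM in spheres and 0.114 CPM in primary cells. Hox genes lying wholly within other genes would be listed at 0 in any cells. How many do is not given here, so the argument holds only for the rest. A whole-chromosome copy number difference carried by most sphere cells is argued against by the medians of the autosomes over genes with a mean of at least 5 CPM. These lay at most 0.13 log2 units from the median of all such genes. A change in a smaller share of the cells would move the medians less and is not argued against. Without the 50 most abundant genes the count of calls was 99.6% of that with them, which decides nothing about a few abundant genes, since the scaling already trims them. Culture format, medium and any difference in culture time, handling or sequencing between the groups coincide, so they cannot be told apart here.

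The third pattern began with H19 and Cdkn1c, which were lower in spheres than in both other groups. A list of imprinted genes made after this was seen fell in 14 and rose in 4 of 19 cases against monolayer (camera p of 0.021 with an estimated correlation) and fell in 12 and rose in 4 against primary cells (0.026); adjusted over the 2 added lists tested, these are 0.042 and 0.052, so the second is over 0.05. Without H19 and Cdkn1c, the unadjusted camera values with an estimated correlation were 0.032 and 0.041. An adjustment over the 2 added lists can bring these over 0.05, so they do not strengthen the result. Lower expression of imprinted genes as a group in spheres may be followed up only as a hypothesis found and tested on the same data. Meg3 was at 253.7, 217.1 and 0.956 CPM in primary cells, monolayer and spheres and Mest at 168.8, 284 and 1.69 CPM, whereas Plagl1 was at 59.81, 60.0 and 640.5 CPM and Dlk1 at 0.632, 0.05 and 38.9 CPM. Igf2 is listed at 0.

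Since Gad2, Grik2 and Cntn3 were among the largest increases, a list of neuronal and synaptic genes was tested; with an estimated correlation it did not pass against monolayer (camera p of 0.16) or primary cells (0.2), with 11 higher and 4 lower, and 10 higher and 4 lower, of 16. Between monolayer and primary cells, the camera values with an estimated correlation were 0.69 for the imprinted and 0.54 for the neuronal list; no Hox gene had enough counts for a test. Of the protein-coding genes wholly covered by opposite-strand genes, 100% had at most 3 counts, which may come from reads in overlapping spans being assigned to neither gene.

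Other splits of the libraries were tried for each count. For spheres against monolayer (6382 higher and 5905 lower), spheres against primary cells (6102 and 6370) and monolayer against primary cells (5389 and 5787), only 1 of 10 splits, the real one, gave as many genes and the highest other gave 0; 10 splits are too few for a share under 0.05. For the 14213 genes differing among the 3 groups, 1 of 100 splits gave as many and the highest other gave 7230. For the 4644 genes higher and 4484 lower in spheres than in both other groups, 1 of 100 did. The highest other, taken over any group and either direction, gave 3534. None of the other splits drawn reached these 3 counts, which tells only that the group labels follow the structure of the libraries. If the libraries of a group are repeats of 1 culture, differences between single cultures are not excluded. The 9 other splits that kept the 3 libraries of a group together held these highest values, and the 90 that kept none together gave 0, which points to the structure of the samples.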
